A study of Homo sapiens with 8 samples.

How the data were processed

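RNA sequencing was performed on BE(2)-C cells under 8 conditions, DMSO and panobinostat at 5, 10 and 15 nM, each at 6 h and at 12 h, with 1 library per condition. The sample labels and the series design give 6 h and 12 h, while a treatment protocol in the labels names a longer time and duplicates; the sample labels were followed. The extraction protocol in the labels names column purification with DNase. Per the submitters' processing notes, bcl2fastq 2.17.1.14, cutadapt, STAR 2.3 and HTSeq were used with hg38. The authors deposited 1 file of whole-number read counts per gene and library, with names that record removed duplicates and a first read. The annotation release, the strand setting and whether reads were single-end are not given in the sources used here. The authors also deposited a table of RPKM values with gene symbols. In 21971 of the 21971 genes with a count in every library these RPKM values were the counts divided by library total and one fixed length per gene (relative tolerance 1e-06), so the table is not an independent measurement, and it served for symbols and for alternatives on the log2 scale.

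Count files held 60554 gene rows, and 60504 had a symbol. Rows that name no gene, for reads outside genes, ambiguous reads and reads aligned to several places, stayed out of library sizes and tests. Together they made 49.3% to 54.6% of all entries, and reads aligned to several places 37.5% to 42.9%, so genes with near-identical copies (HBA1, metallothionein, HSPA1A and histone genes among those in the lists) are uncertain. Gene totals ran from 11372996 to 15355487 counts, and a floor of 3 counts is 0.195 to 0.263 CPM. Duplicates were removed, per the file names, and no gene exceeded 1.84 reads per exonic base of the GENCODE release 29 exon union in any library.

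The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with a minimum count of 10, robust quasi-likelihood fits, and Benjamini-Hochberg adjusted p-values against 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Treatment and time were terms of one fit of 8 libraries. The effects at 6 h and 12 h and their difference came from a fit of 4 cells, each dose from a fit with dose as a factor and time, and the dose trend from a linear term in the 6 treated libraries with time. With 1 library per condition, libraries of different dose supply the spread, a lone DMSO library is assumed to vary like the others, and p-values do not cover repeated cultures. File-name run tags were shared by the 6 h libraries, while the DMSO library and the treated libraries at 12 h each carried another tag. Whether these tags mark sequencing runs is not stated in the sources used here. If they do, run follows time, and at 12 h also treatment. The comparison at 6 h lies within 1 tag.

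Comparisons, tests, 33 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named in the closing section. Lists with at least 5 tested members were tested with limma 3.58.1 (camera, preset correlation 0.01, log-CPM with prior count 2), with an estimated correlation beside it; fry was an alternative. AVEN, CDKN1A, MYCN and HDAC1 to HDAC11 were always named. For the treatment effect the rule took the 10 largest rises and the 10 largest falls among genes with a symbol, adjusted p under 0.05, mean CPM of at least 5 and one sign in all 6 treated libraries against the DMSO library of their time. For time, dose trend and the difference it took 5 each way with one sign at all treatments or ordered at both times, and for each list up to 4 members with the smallest adjusted p. Some genes that the rule names are not reported here. Where DMSO held 0 counts a lower bound against 3 counts per DMSO library is given, and with 1 to 3 counts a ratio with an exact 95% interval.

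Each fit was tested on simulated counts of the real genes with 2-fold and 4-fold changes. For the treatment effect 65.3% of 2-fold and 91.4% of 4-fold changes were recovered among 18777 genes, and for the time effect 71.7% and 94.9% among 18837 genes. Unchanged genes were called as well: 14 for the treatment effect, 7 for time and 24 for the dose trend, the most of any fit. Few genes were changed, 98 by 2-fold and 93 by 4-fold for the treatment effect. The real data called many more, so these rates may not carry over. Alternatives were DESeq2 size factors, library totals, no filter, DESeq2 1.42.0, limma-voom, limma on log2 RPKM with pseudocounts of 1 and 0.1, leaving out each library, and, for single results, other codings of dose and time. Without the DMSO library of either time, the treatment effect is that of the other time alone. It then repeats the effect at that time and does not test the pooled effect. After the data were seen, TMM factors from genes under 0.1 reads per exonic base were added, and for the time effect a fit with dose as a block. Figures were drawn with matplotlib 3.10.9.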

Results

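Gene expression was measured by RNA sequencing of total RNA from BE(2)-C, a human neuroblastoma cell line with amplified MYCN. The cells received DMSO, the solvent control, or panobinostat, a histone deacetylase (HDAC) inhibitor, at 5, 10 or 15 nM for 6 h or 12 h. Each dose and time had 1 library, 8 in all, so no condition was replicated. Total gene counts were 13368670 and 13310516 in the DMSO libraries at 6 h and 12 h. In the order 5, 10 and 15 nM the treated libraries held 15355487, 14308540 and 15065508 counts at 6 h and 14397784, 13363513 and 11372996 at 12 h. Genes with at least 1 count numbered 27093 and 26738 in the DMSO libraries, and between 28112 and 29431 in the treated libraries. Libraries of different dose or time supplied the spread for every test, so the p-values measure differences against that spread and not against repeated cultures.

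The series title names AVEN, which encodes an inhibitor of caspase activation, and the first question was whether its transcript changed under panobinostat. AVEN (ENSG00000169857.7) is a protein-coding gene on the minus strand of chromosome 15, from 33866227 to 34039176 in the GENCODE release 29 annotation of GRCh38. Its level fell to 0.352 of the DMSO level, a log2 fold change of -1.51 (SE 0.17), with edgeR's quasi-likelihood test giving an adjusted p of 0.000332, and was lower in 6 of 6 treated libraries. At 6 h AVEN stood at 37.7 CPM (counts scaled by library size) in DMSO and at 15.2, 15.5 and 17.4 CPM with 5, 10 and 15 nM. At 12 h it stood at 34.9 CPM in DMSO and at 12.6, 9.89 and 8.07 CPM. The log2 fold change was -1.26 (SE 0.21) at 6 h and -1.80 (SE 0.21) at 12 h. These differed by -0.54 (SE 0.31), with an edgeR adjusted p of 0.838. Among the panobinostat libraries alone AVEN was lower at 12 h than at 6 h by a log2 difference of -0.65 (edgeR adjusted p = 0.00344), where time and run tag cannot be told apart. Among the treated libraries the slope of AVEN on dose was -0.08 log2 units per 5 nM (SE 0.08, edgeR adjusted p = 0.522). Without the 15 nM library at 6 h that slope was -0.23 and passed the threshold (edgeR adjusted p = 0.048), while without the 5 nM or the 15 nM library at 12 h it turned to 0.04 and 0.02 (edgeR adjusted p = 0.75 and 0.91). With DMSO entered as dose 0 it was -0.51 and passed (edgeR adjusted p = 0.0149). Within the 6 h libraries alone, which share a run tag, AVEN had a log2 fold change of -1.26 (edgeR adjusted p = 0.0034).

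**Figure D1:**
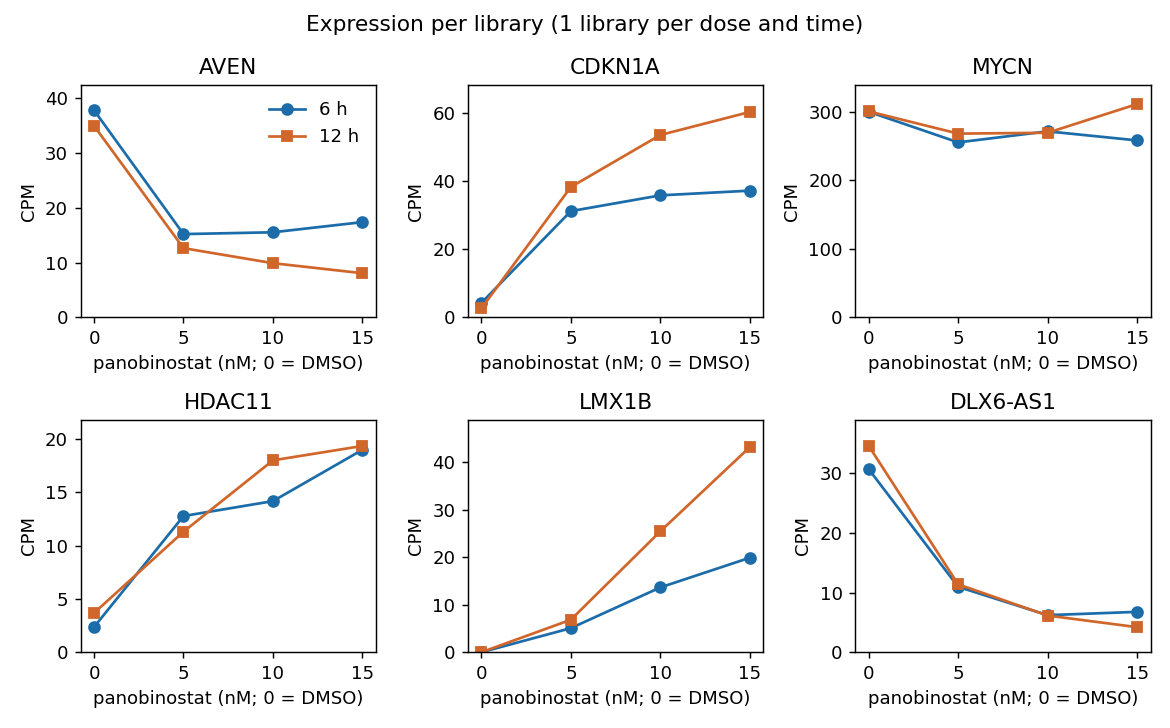
CPM of 6 genes (vertical axes) against panobinostat dose in nM (horizontal axes, 0 being DMSO), with 1 point per library and lines joining the libraries of one time (circles 6 h, squares 12 h). AVEN lies between 8.07 and 17.4 CPM in the treated libraries against 34.9 and 37.7 in DMSO, while CDKN1A rises from 4.28 and 2.69 CPM to 31.2 or more.

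Panobinostat against DMSO, with time as a term, addressed which genes responded at any dose. Of 19213 genes tested, 5123 were higher and 3965 lower in treated cells, and 2677 of the former and 551 of the latter differed at least 2-fold. The genes with the largest rises had few or no counts in DMSO. LMX1B, a LIM-homeodomain transcription factor, had 0 counts in both DMSO libraries and a mean of 19.0 CPM in treated libraries, at least 82.7-fold higher against a floor of 3 counts per DMSO library. By the same measure FXYD7, a regulator of the sodium-potassium pump, was at least 45.4-fold higher, PHOSPHO1, a phosphatase of bone mineralisation, at least 32.4-fold, KIF12 at least 32.0-fold, COX6B2 at least 30.2-fold and GABRB2, a GABA-A receptor subunit, at least 29.5-fold. MICB, a ligand of the NKG2D receptor on natural killer cells, had 2 counts in DMSO and 1209 in treated libraries, a ratio of 187 with an exact 95% counting interval of 51.7 to 1546. NXPH4 and GPR4 each had 1 count in DMSO, with ratios of 216 (38.7 to 8552) and 195 (35.0 to 7733). These floors and intervals cover counting error only. PTRF, a caveolar coat protein, went from 0.229 and 0.154 CPM in DMSO to between 28.3 and 73.3 CPM, with a log2 fold change of 7.89 (SE 0.57, edgeR adjusted p = 5.55e-05). LMX1B and GPR4 missed the threshold without the DMSO library at 12 h (edgeR adjusted p = 0.05 and 0.057), and KIF12 without either DMSO library (0.0673 and 0.0792). Both LMX1B and KIF12 also missed it with no filter on low counts, LMX1B, KIF12, COX6B2, NXPH4 and GPR4 in the 12 h libraries alone, and FXYD7, PTRF and MICB with dose as a number.

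The falls were smaller. IGF2-AS had a log2 fold change of -2.40 (SE 0.40, edgeR adjusted p = 0.00219), and TMEM204 one of -2.31 (SE 0.40). LANCL2 fell by 2.19 on the log2 scale (SE 0.20, edgeR adjusted p = 0.000148), from 68.9 and 51.0 CPM in DMSO to between 7.89 and 16.4 CPM. GPR22, LRRTM1, DLX6-AS1, RTL1, LAMP5-AS1, SCRT2, a neuronal repressor of the Snail family, and KCTD15 fell by 1.99 to 2.15 on the log2 scale. IGF2-AS, DLX6-AS1 and LAMP5-AS1 are antisense genes, and as the strand setting of the counting is not given in the sources used here, their values are uncertain. LRRTM1 missed the threshold without the DMSO library at 6 h (log2 -1.77, edgeR adjusted p = 0.0989), and SCRT2 without that at 6 h or at 12 h (-1.80 and -2.29, edgeR adjusted p = 0.0955 and 0.0521). In the 12 h libraries alone IGF2-AS, TMEM204, GPR22, LRRTM1, DLX6-AS1, RTL1, SCRT2 and KCTD15 did not pass. Leaving out the DMSO library of either time leaves the treatment effect at the other time alone, so such values do not test the pooled effect. Fewer genes passed in such fits and in the libraries of either time alone. The share of higher genes depended on the scaling: with TMM factors taken only from genes with few reads per exonic base, a choice made after the data were seen, the median of all genes moved to -0.21 and the counts were 3571 higher and 7502 lower. With the standard factors those genes were more often higher than lower, 2629 against 793 under 0.05 reads per base and 744 against 518 from 0.05 to 0.1. Factors centred on them shift fold changes against DMSO downward, here and below. A balance that turns with these factors follows at least partly from that choice.

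Of the genes fixed in advance, CDKN1A, the p21 cell cycle inhibitor, had a log2 fold change of 3.57 (SE 0.31, edgeR adjusted p = 0.00011) and was higher in 6 of 6 treated libraries. HDAC11, the class IV deacetylase, rose by 2.39 (SE 0.30, edgeR adjusted p = 0.000589), from 2.37 and 3.68 CPM in DMSO to between 11.3 and 19.4 CPM. Smaller changes passed the test for HDAC3 (log2 0.41, SE 0.10), HDAC6 (0.26, SE 0.08), HDAC1 (0.21, SE 0.05) and HDAC7 (-0.61, SE 0.17). With the TMM factors from sparsely read genes, HDAC1 turned to -0.01 and HDAC2, at 0.01 with the standard factors, to -0.21, and HDAC3 and HDAC6 no longer passed, at 0.19 and 0.04. With either DMSO library left out, HDAC1, HDAC3, HDAC6 and HDAC7 did not pass: without that at 6 h their values were 0.19, 0.34, 0.26 and -0.66, and without that at 12 h 0.16, 0.42, 0.19 and -0.62. In the 12 h libraries alone they did not pass either, at 0.22, 0.36, 0.29 and -0.63. HDAC1 and HDAC6 also missed the threshold in the 6 h libraries alone (0.17 and 0.19, edgeR adjusted p = 0.103 and 0.123) and with no filter on low counts (0.16 and 0.20, edgeR adjusted p = 0.0856 and 0.0852), and HDAC6 on log2 RPKM with a pseudocount of 1 (0.21, limma adjusted p = 0.052). HDAC4, HDAC5, HDAC8, HDAC9 and HDAC10 had log2 fold changes between -0.16 and 0.18 and did not pass. With the TMM factors from sparsely read genes HDAC4 (-0.37, edgeR adjusted p = 0.00189), HDAC8 (-0.37, edgeR adjusted p = 0.00369) and HDAC9 (-0.38, edgeR adjusted p = 0.047) passed, and HDAC5 turned from 0.18 to -0.04. HDAC4 also passed with no filter on low counts (-0.20, edgeR adjusted p = 0.0405) and without the 5 nM library at 6 h (-0.18, 0.0317), and HDAC5 without the 5 nM library at 12 h (0.23, 0.0227). With dose as a number HDAC4, HDAC5 and HDAC9 passed, at -0.075, 0.11 and -0.15 per 5 nM. MYCN stood at 300.2 and 301 CPM in DMSO and between 256 and 311 CPM in treated libraries, with a log2 fold change of -0.14 (SE 0.07, edgeR adjusted p = 0.106). Without the 15 nM library at 12 h it was -0.18 and passed (edgeR adjusted p = 0.00831). It also passed in the 6 h libraries alone (-0.22, edgeR adjusted p = 0.0344), with no filter on low counts (-0.20, edgeR adjusted p = 0.0267) and with the TMM factors from sparsely read genes (-0.36, edgeR adjusted p = 0.00485). MYCN had between 1.37 and 1.51 reads per exonic base in each of the 8 libraries, where the highest value of any gene and library was 1.84. Library totals ran from 11372996 to 15355487 counts. If duplicate removal limits such counts, a question left open below, the CPM of MYCN falls as totals rise. Neither the missing call nor these falls can be told apart from such a limit.

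Gene lists fixed before the data were examined addressed which groups of genes moved. As background, of 13830 protein-coding genes tested 31.6% were higher and 24.4% lower, and of 6879 genes above a mean of 50 CPM 20.3% and 32.7%. Counts near these shares do not mark out a list. Of 31 lists with at least 5 tested members, 10 passed limma's camera test with a preset inter-gene correlation, 4 of them upward and 6 downward. With an estimated correlation none passed, and the smallest adjusted p was 0.545. Markers of the mesenchymal-type neuroblastoma state had 14 of 21 tested members higher and 3 lower (camera adjusted p = 0.000454; adjusted p = 0.545 with an estimated correlation). Adjusted over the list alone, 15 were higher and 3 lower. The Notch receptors NOTCH2 (log2 fold change 6.15, SE 0.24) and NOTCH3 (4.93, SE 0.27) and the Hippo-pathway coactivators YAP1 (4.16, SE 0.36) and WWTR1 (1.82, SE 0.13) were among those higher. Markers of fibroblasts and endothelium, cells that a mesenchymal list could reflect, had 4 of 8 tested members higher and 1 lower. COL1A1, on both lists, had a log2 fold change of 5.13 (SE 0.51), and COL3A1, chosen after its value was seen, one of -0.04 (SE 0.42). With the DMSO library of 6 h left out 13 members of the mesenchymal list were higher and 1 lower, and with that of 12 h left out 13 and 2; of the fibroblast and endothelial markers 4 and 3 were higher and 0 lower.

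Adrenergic neuroblastoma transcription factors, the regulators of the sympathetic state, had 12 of 22 members lower and 3 higher (camera adjusted p = 0.0211; adjusted p = 0.637 with an estimated correlation). Adjusted over the list alone, 14 were lower and 4 higher. MEIS2 fell by 0.86 (SE 0.15) and ISL1 by 0.38 (SE 0.06) on the log2 scale, and MEIS2 missed the threshold without the DMSO library at 6 h (-0.71, edgeR adjusted p = 0.0514). Neuronal progenitor genes had 12 of 17 members higher and 3 lower, the same counts as adjusted over the list alone (camera adjusted p = 0.0249; adjusted p = 0.545 with an estimated correlation). The Notch ligands JAG1 (log2 fold change 3.51, SE 0.37) and DLL1 (1.98, SE 0.26), the Notch target HES1 (0.75, SE 0.08) and the intermediate filament gene NES (0.99, SE 0.07) were higher. Markers of Schwann cells and glia had 4 of 8 tested members higher and 1 lower (camera adjusted p = 0.154). Adrenergic factors called lower numbered 2 without the DMSO library at 6 h and 11 without that at 12 h, with 0 and 1 higher. In the same order 7 and 7 progenitor genes were higher and 1 and 2 lower, and of the Schwann cell and glia markers 2 and 3 were higher and 0 lower.

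The list of MYC and MYCN targets and ribosome biogenesis genes had 19 of 32 members lower and 0 higher, and 22 lower when adjusted over the list alone (camera adjusted p = 1.97e-05; adjusted p = 0.545 with an estimated correlation). DKC1, a subunit of the telomerase and pseudouridylation complex, fell by 0.45 (SE 0.07) and CAD, of pyrimidine synthesis, by 0.77 (SE 0.13) on the log2 scale. G2/M and mitosis genes had 19 of 31 members lower and 0 higher, also when adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.571 with an estimated correlation), with PLK1 at -0.52 (SE 0.09), KIF20A at -0.39 (SE 0.06) and FOXM1 at -0.31 (SE 0.05). PLK1 missed the threshold without the DMSO library at 6 h (-0.38, edgeR adjusted p = 0.0501). G1/S and DNA replication genes had 16 of 35 lower and 4 higher, again the same adjusted over the list alone (camera adjusted p = 0.0211; adjusted p = 0.545 with an estimated correlation). MCM5 of the replicative helicase fell by 0.46 (SE 0.06) and the kinase gene CDK4 by 0.31 (SE 0.05) on the log2 scale. Nuclear-encoded oxidative phosphorylation genes had 9 of 32 lower and 0 higher, and 7 lower adjusted over the list alone (camera adjusted p = 0.00315; adjusted p = 0.571 with an estimated correlation). CYC1 of complex III fell by 0.31 (SE 0.05) on the log2 scale. Without the DMSO library at 6 h and without that at 12 h, the members called lower numbered 13 and 10 in the list of MYC and MYCN targets and ribosome biogenesis, 4 and 18 in G2/M, 8 and 13 in G1/S and 5 and 5 in oxidative phosphorylation. They numbered 31, 26, 24 and 28 with the TMM factors from sparsely read genes.

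Histone acetyltransferases and BET readers had 10 of 15 members lower and 2 higher, and 10 and 3 adjusted over the list alone (camera adjusted p = 0.00794; adjusted p = 0.545 with an estimated correlation). KAT5 fell by 1.04 (SE 0.15), KAT6B by 0.86 (SE 0.07) and CREBBP by 0.72 (SE 0.10) on the log2 scale. Immediate early genes had 18 of 25 higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.00261; adjusted p = 0.545 with an estimated correlation). NR4A3 (log2 fold change 1.70, SE 0.17), NR4A2 (1.53, SE 0.18) and KLF4 (1.34, SE 0.14) were among them. Antigen presentation genes had 12 of 18 higher and 0 lower, and 12 and 2 adjusted over the list alone (camera adjusted p = 0.00261; adjusted p = 0.545 with an estimated correlation). TAP1, the peptide transporter (4.65, SE 0.37), HLA-E (4.49, SE 0.28) and the NKG2D ligands ULBP1 (3.45, SE 0.21) and ULBP2 (3.49, SE 0.30) were higher. Markers of blood cells had 2 of 3 tested members higher and 0 lower. HBA1, with 0 counts in DMSO and 46 in treated libraries, was at least 2.49-fold higher, and missed the threshold without the DMSO library at 12 h (edgeR adjusted p = 0.0737). When the DMSO library of 6 h or that of 12 h was left out, 6 and 8 acetyltransferase and BET reader genes were lower and 0 higher, 9 and 13 immediate early genes were higher and 0 and 1 lower, 10 and 7 of 19 antigen presentation genes were higher and 2 and 0 lower, and 2 and 1 blood markers were higher. Of the blood markers 1 was higher without the 10 nM or the 15 nM library at 12 h. Of the antigen presentation genes 11 were higher and 4 lower with the TMM factors from sparsely read genes.

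**Figure D2:**
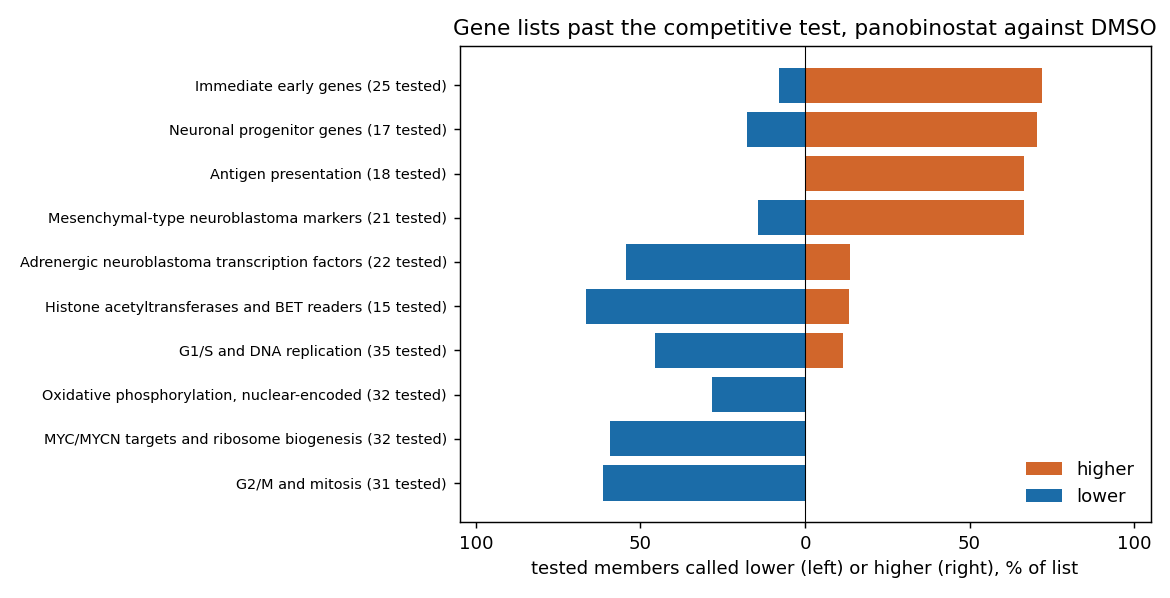
Share of tested members (horizontal axis, percent) called lower (left, blue) or higher (right, orange) with panobinostat, for the 10 lists that passed the camera test with a preset correlation. MYC and MYCN targets and ribosome biogenesis genes, G2/M genes and oxidative phosphorylation genes had 0 members higher, and antigen presentation genes 0 lower.

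Lists on cell death did not pass the camera test. Pro-survival genes, a list that holds AVEN, had 8 of 14 members lower and 2 higher, and 9 and 3 adjusted over the list alone (camera adjusted p = 0.117). HAX1 fell by 0.39 (SE 0.06) on the log2 scale, while the inhibitor of apoptosis BIRC3 had a log2 fold change of 4.33 (SE 0.47) and the co-chaperone BAG3 one of 0.76 (SE 0.12). Pro-death genes had 9 of 26 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.181). APAF1, the apoptosome scaffold (1.03, SE 0.08), the death receptor gene TNFRSF10A (2.84, SE 0.23) and BMF (2.92, SE 0.33) were higher, and DIABLO fell by 1.10 (SE 0.09). CDK inhibitors and growth arrest genes had 11 of 18 higher and 4 lower, the same adjusted over the list alone (camera adjusted p = 0.274). CDKN2B had a log2 fold change of 2.31 (SE 0.37), and CDKN2C fell by 0.71 (SE 0.09) and CDKN1B by 0.97 (SE 0.18). Leaving out the DMSO library of 6 h or that of 12 h left 4 and 6 pro-survival genes lower, and 3 and 7 CDK inhibitor and growth arrest genes higher. With the TMM factors from sparsely read genes 9 pro-death genes were higher and 8 lower. Of the list members named here, MEIS2, ISL1, DKC1, CAD, PLK1, KIF20A, FOXM1, MCM5, CDK4, CYC1, KAT5, HBA1, HAX1, BAG3, CDKN2B, CDKN2C and CDKN1B did not pass in the 12 h libraries alone. With dose as a number NOTCH2, NOTCH3, YAP1, WWTR1, ISL1, HES1, CYC1, NR4A3, TAP1, HLA-E, ULBP1, APAF1 and TNFRSF10A did not pass.

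The 2 times were then compared. At 6 h 3322 of 20050 genes were higher and 2349 lower, and at 12 h 2991 were higher and 1934 lower. Both times called 2169 genes higher, where 496 would be shared by independent lists, and 1200 lower, where 227 would. The DMSO libraries of the 2 times are separate, but both effects come from the same fit with a shared spread. Sharing beyond that of independent lists can therefore come from the fit. Opposite directions were called for 4 genes higher at 6 h and lower at 12 h and for 1 gene the other way. Across genes, which are not independent replicates, the fold changes had Pearson's r of 0.819 and Spearman's rho of 0.781. CDKN1A had log2 fold changes of 2.99 at 6 h and 4.20 at 12 h, and HDAC11 of 2.66 and 2.10. In the test of the difference 0 genes passed in edgeR, with 1289 at an unadjusted p under 0.05, 0 passed in limma-voom and 1 in DESeq2. On simulated counts the same test recovered 30.2% of 2-fold and 68.7% of 4-fold differences among 19529 genes, and called 9 unchanged genes. Of the adrenergic transcription factors 11 of 22 were lower and 1 higher at 6 h (camera adjusted p = 0.00296; adjusted p = 0.553 with an estimated correlation), and 2 were lower at 12 h (camera adjusted p = 0.15). Adjusted over the list alone, 13 were lower at 6 h and 0 at 12 h. Of the G2/M genes 18 of 31 were lower at 6 h (camera adjusted p = 3.55e-06; adjusted p = 0.362 with an estimated correlation) and 4 at 12 h (camera adjusted p = 0.0378; adjusted p = 0.569 with an estimated correlation). Adjusted over the list alone, 21 were lower at 6 h and 0 at 12 h. The difference of the effect, 12 h minus 6 h, had a median of 0.19 for the adrenergic list (camera adjusted p = 0.0215; adjusted p = 0.749 with an estimated correlation) and of 0.16 for the G2/M list (camera adjusted p = 0.000154; adjusted p = 0.575 with an estimated correlation). Mitochondrially encoded genes had a median log2 fold change of -0.211 at 6 h and -0.04 at 12 h, a median difference of 0.174. Each treated library at 6 h held more counts than its DMSO library, while at 12 h the 15 nM library held fewer. If duplicate removal limits genes with many reads per exonic base, library depth could give such contrasts. This was not tested for these lists. The numbers of genes called at each time moved with single libraries. At 6 h 2347, 2895 and 3367 genes passed without 10 nM at 6 h, 15 nM at 6 h and 10 nM at 12 h, and at 12 h 2652, 7430 and 1984 without 10 nM at 6 h, 5 nM at 12 h and 10 nM at 12 h. Scaling by library totals gave 3736 higher and 1631 lower genes at 6 h and 3361 and 1133 at 12 h, while TMM factors from sparsely read genes gave 2565 and 4908 at 6 h and 2461 and 5508 at 12 h.

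**Figure D3:**
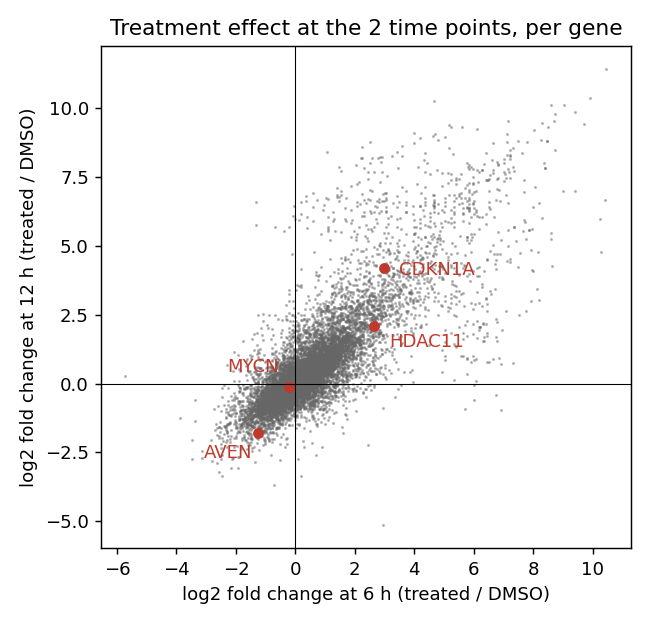
Fitted log2 fold change of panobinostat against DMSO at 6 h (horizontal axis) and at 12 h (vertical axis), 1 grey point for each of 20050 genes, with AVEN, CDKN1A, HDAC11 and MYCN in red. AVEN lies at -1.26 and -1.80 and CDKN1A at 2.99 and 4.20, and the values of genes with 0 counts in DMSO depend on the prior count of the fit.

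Each dose was set against DMSO, and the dose trend was tested within the treated libraries. At 5 nM 4376 genes were higher and 2846 lower, at 10 nM 5252 and 4142, and at 15 nM 5674 and 4512. With TMM factors from sparsely read genes the balance turned, to 3128 and 7038 at 5 nM, 3750 and 7351 at 10 nM and 4121 and 6935 at 15 nM. The 3 comparisons share both DMSO libraries. Without the 5 nM library at 6 h, 3492 genes passed at 5 nM. From 5 to 15 nM, 2804 of 19080 genes rose and 3047 fell with dose. This balance turned to 3109 and 2679 with the TMM factors from sparsely read genes, to 2988 and 2904 with library totals and to 2197 and 1991 on log2 RPKM with a pseudocount of 1. ACSBG1, an acyl-CoA synthetase, rose by 1.17 log2 units per 5 nM (SE 0.10, edgeR adjusted p = 3.51e-05), from 3.57 to 13.7 CPM at 6 h and from 6.83 to 46.6 CPM at 12 h. BAIAP3, from 9.03 to 38.4 CPM at 6 h and from 7.04 to 54.3 CPM at 12 h, KIF12 (1.11, SE 0.18), LMX1B (1.09, SE 0.12) and FAM46C (1.09, SE 0.17) also rose, though BAIAP3 missed the threshold with no filter on low counts (edgeR adjusted p = 0.082). SCRT2, from 3.83 to 0.855 CPM at 6 h and from 6.70 to 2.10 CPM at 12 h, the muscarinic receptor gene CHRM1 (-0.90, SE 0.10), LRRTM1 (-0.87, SE 0.10) and ITPRIPL2 (-0.81, SE 0.10) fell with dose. Adrenergic transcription factors had 10 of 22 members falling with dose and 1 rising, the same adjusted over the list alone (camera adjusted p = 0.00642; adjusted p = 0.78 with an estimated correlation). Replication-independent and polyadenylated histone genes had 8 of 18 rising and 1 falling (camera adjusted p = 0.00464, or 0.78 with an estimated correlation). Adjusted over the list alone, 9 rose and 1 fell. Mitochondrially encoded genes, with 0 of 13 called, rose by a median of 0.09 per 5 nM (camera adjusted p = 0.0291, or 0.786 with an estimated correlation). The histone list had a median of 0.14. At 12 h library totals fell with dose, from 14397784 to 11372996 counts. If duplicate removal limits genes with many reads per exonic base, their CPM would rise with dose there. List trends upward with dose were not tested apart from this. Without the 5 nM or the 15 nM library at 12 h, 3840 and 3309 genes passed the trend test, and in DESeq2 3746.

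The time effect, averaged over treatments, comprised 422 genes higher and 176 lower at 12 h than at 6 h. NID1, a basement membrane protein, was higher at 12 h by 1.98 (SE 0.23, edgeR adjusted p = 0.014), at 0.153 and 0.154 CPM in the DMSO libraries, between 2.73 and 3.70 CPM in treated libraries at 6 h and between 10.2 and 16.2 CPM at 12 h. The DMSO values of NID1 barely differed and lay below the floor of 3 counts, 0.229 and 0.230 CPM. Its time effect therefore came from the treated libraries and does not show a change with time in DMSO. SCN4B (1.77, SE 0.21), CACNG7 (1.72, SE 0.29), SH3GL3 (1.62, SE 0.13) and COL1A1 (1.53, SE 0.29) were higher as well. GRIN2C (-1.29, SE 0.20), TNFRSF13C (-1.22, SE 0.26), POLN (-1.07, SE 0.22), HFM1 (-0.98, SE 0.14) and ANGPT2 (-0.97, SE 0.14) were lower. This count rests on single libraries: it was 0 without 5 nM at 6 h, 10 nM at 6 h or 10 nM at 12 h, 3 without 15 nM at 6 h, 83 without 15 nM at 12 h, and 1646 and 1644 without the DMSO library at 6 h and 12 h. None of the 10 named genes passed without a treated library of 6 h or without 10 nM at 12 h. CACNG7, COL1A1, GRIN2C, TNFRSF13C, POLN and HFM1 also missed the threshold without 15 nM at 12 h, TNFRSF13C without 5 nM at 12 h and COL1A1 with no filter on low counts. On log2 RPKM 0 genes passed with either pseudocount, and DESeq2 gave 1256. With dose as a block, a fit chosen after the data were seen that pairs the 6 h and 12 h library of each treatment, 1788 genes were higher and 1222 lower at 12 h. Among the panobinostat libraries alone 6304 genes differed between the times, and the run tags of the libraries differ between the times, so time and run tag cannot be told apart.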

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

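The search of the lists below for differences between the times was chosen after the results had been seen. Reads aligned uniquely outside annotated genes, which the comparisons above do not use, took a larger share in each treated library than in the DMSO library of its time. At 6 h the share of uniquely aligned reads was 14.4% in DMSO and 15.575%, 15.182% and 15.509% with 5, 10 and 15 nM. At 12 h it was 13.8% in DMSO and 15.1%, 14.669% and 13.954%. Of the gene lists, 8 differed in the treatment effect between 12 h and 6 h by camera with a preset correlation, and 0 with an estimated one, where the smallest adjusted p was 0.575. The median difference, 12 h minus 6 h on the log2 scale, was 0.158 for G2/M genes, 0.189 for adrenergic transcription factors, 0.278 for mesenchymal-type markers, -0.174 for ER stress and integrated stress response genes, 0.214 for metallothionein and oxidative stress genes and -0.371 for immediate early genes. It was 0.585 for fibroblast and endothelial markers and 1.123 for epithelial, liver and muscle markers. Mitochondrially encoded genes, a list that did not pass, had a median difference of 0.174. For lists with many reads per exonic base, library depth could give differences of this size, as described above. In the test of the difference between the times no single gene was called in edgeR or limma-voom, and 1 was called in DESeq2. No named gene moved one way in each treated library at 6 h and the other way in each at 12 h. The naming rule largely fixed this outcome. Genes named for the treatment effect had to keep one sign in every treated library, and list members were taken by smallest adjusted p. The absence of such a gene among those named therefore cannot decide whether genes reversed between the times.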

How the results depend on the processing

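The TMM factors from genes with few reads per base and the block by dose were chosen after seeing the data; other alternatives were planned. AVEN fell and passed under each alternative for the treatment effect, from -1.804 to -1.265 when single libraries were left out, and at -0.512 per 5 nM with dose as a number. Leaving out single libraries gave 4950 to 10108 genes for the treatment effect, 2347 to 7543 at 6 h, 1984 to 7430 at 12 h, 3492 to 7509 at 5 nM, 6385 to 9377 at 10 nM, 7712 to 10145 at 15 nM, 3309 to 7030 for the dose trend, 0 to 1646 for time and 0 for the difference. The effect at a time, and the difference, cannot be estimated without that time's DMSO library. Without it the treatment effect is that of the other time alone. The treatment effect had 9088 genes, 1629 with 12 h libraries alone and 3228 at 2-fold or more. With TMM factors from sparsely read genes 7969 passed at 12 h, against 4925, and HDAC1 and HDAC2 turned to -0.01 and -0.211. DESeq2 gave 1 gene for the difference, against 0, 3746 for the dose trend, against 5851, and 1256 for time, against 598. Time gave 0 genes on RPKM with either pseudocount and 6304 among panobinostat libraries, and with dose as a block, pairing the times, 3010, among them all 598 in the same direction. Of the lists, 10 passed in camera, 0 with an estimated correlation, 22 with directional and 30 with mixed fry, which do not compare a list with other genes. The cause was not tested, except that fewer libraries entered when some were left out and 2-fold adds a condition. Sparsely read genes were also more often higher than lower, so TMM factors from them shift fold changes against DMSO downward. For named genes, 3192 of 3500 values stayed on their side of the threshold, 284 fell below it, 22 rose past it and 2 reversed. DMSO floors limit the folds of genes with 0 counts there.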

Other observations

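Tests of run, of library depth, of reads outside genes and of other cell types in this part were chosen after their results had been seen; the others were written before. Further lists did not pass the camera test for the treatment effect but held called genes. So did protein-coding genes as a whole, with 31.6% higher and 24.4% lower. Autophagy and lysosome genes had 15 of 35 members higher and 4 lower, and 16 and 4 adjusted over the list alone (camera adjusted p = 0.183), with GABARAPL1 at 2.46 (SE 0.12) and WIPI1 at 1.90 (SE 0.24). In the dose trend 12 of these rose and 1 fell (camera adjusted p = 0.00529, or 0.786 with an estimated correlation). The limit of library depth given for the dose trend holds here too. Glycolysis and hypoxia genes had 8 of 25 higher and 4 lower (camera adjusted p = 0.97), with NDRG1 at 2.54 (SE 0.20) and SLC2A3 at 1.21 (SE 0.12). Catecholamine synthesis and chromaffin genes had 9 of 18 lower and 4 higher (camera adjusted p = 0.199), with the synthesis enzyme DBH at -0.61 (SE 0.11) and MAOA, which degrades amines, at 4.07 (SE 0.35). Neuronal differentiation and neurite genes had 9 of 34 higher and 4 lower (camera adjusted p = 0.408), with NGFR at 4.99 (SE 0.35) and MAPT at 0.74 (SE 0.06). Leaving out the DMSO library of 6 h or that of 12 h left 7 and 7 autophagy genes higher and 2 and 4 lower, and 6 and 2 catecholamine genes lower and 3 and 2 higher; without the 5 nM library at 12 h 7 glycolysis genes were lower. With the TMM factors from sparsely read genes the balance turned, to 4 higher and 11 lower for autophagy, 8 and 15 for glycolysis and 9 and 14 for neuronal differentiation.

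Homologous recombination and checkpoint genes had 8 of 27 lower and 1 higher (camera adjusted p = 0.0907), with NBN at -0.75 (SE 0.14), or -0.54 and past the threshold no longer (edgeR adjusted p = 0.0629) without the DMSO library at 6 h. Polycomb and DNA methylation genes had 8 of 21 lower and 3 higher, and drug efflux genes 4 of 13 each way. ER stress and integrated stress response genes had 5 of 23 higher and 1 lower, heat shock and proteostasis genes 1 of 15 higher and 5 lower, and cholesterol synthesis genes 4 of 23 higher and 2 lower. Metallothionein and oxidative stress genes had 6 of 19 higher and 4 lower, retinoid genes 4 of 13 higher and 3 lower, HDAC and sirtuin genes 7 of 18 higher and 3 lower, and replication-independent and polyadenylated histone genes 4 of 18 higher and 3 lower. Of the mitochondrially encoded genes 0 of 13 were called. Their share of counts was lowest in the largest library (0.127%, 5 nM at 6 h) and highest in the smallest (0.169%, 15 nM at 12 h). If duplicate removal limits their counts, a response could not show. The calls of these genes, here and below, therefore cannot decide whether they responded. Cancer-testis and germline genes had 3 of 4 tested members higher. Median, mean and camera direction differed in sign for catecholamine, heat shock, cholesterol, metallothionein, glycolysis, retinoid and histone genes. Epithelial, liver and muscle markers had 4 of 7 higher, but 2 without the DMSO library at 6 h and 1 without that at 12 h. In the same order the recombination list had 1 and 8 members lower and 0 higher, the Polycomb list 4 and 5 lower, ER stress 1 and 5 higher, heat shock 3 and 1 lower, cholesterol 2 and 1 higher, metallothionein 5 and 2 higher, retinoid 3 and 2 higher, drug efflux 3 and 1 higher, HDAC and sirtuin 2 and 3 higher, histone 1 and 1 higher and cancer-testis 3 and 2 higher. Without the 10 nM library at 6 h or at 12 h 5 and 4 recombination genes were lower, and without 15 nM at 12 h 8 heat shock and 3 mitochondrially encoded genes. With the TMM factors from sparsely read genes more members were lower than higher for ER stress (10 and 3), cholesterol (13 and 1), metallothionein (10 and 5), retinoid (6 and 3), HDAC and sirtuin (7 and 4) and histone genes (8 and 1), and 11 mitochondrially encoded genes were lower. The same held for recombination (20 and 0), Polycomb (15 and 3), heat shock (11 and 1) and drug efflux genes (5 and 3). Of the genes named here DBH and NBN did not pass in the 12 h libraries alone, and GABARAPL1, SLC2A3, MAOA, NGFR and MAPT not with dose as a number.

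Exchanging libraries between the groups gave fewer genes in both comparisons tested this way. For the treatment effect 1 of 28 splits of the libraries into 2 and 6 gave as many genes as the real one, 9088, and the highest of the others gave 0. For time 1 of 35 splits into 4 and 4 gave as many as the real one, 598, and the highest of the others, 95, was the split that pairs the 6 h DMSO library with the treated 12 h libraries. Both shares are under 1 in 20 over all splits, but they are the smallest these splits allow. Every other split mixes treated with DMSO libraries, or 6 h with 12 h libraries, so the compared effect enters the spread. The shares therefore cannot decide whether the calls arose by chance. Exchanging libraries only within a time leaves 16 splits for the treatment effect, and swapping times only within a dose leaves 8 for time; the real split gave the most genes in both, with 0 and 95 as the highest of the others, but these are too few for a share under 0.05. Run tags remain tied to time and, at 12 h, to treatment.

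Genes with many reads per exonic base had fold changes closer to 0. The interquartile range of log2 fold changes was 1.47 for 7812 genes under 0.05 reads per base and 0.095 for 64 genes above 1, and 0 of the latter passed at 2-fold. Counting noise as the whole cause is argued against by the spread beyond the standard errors, which in genes under 0.1 reads per base was 7.136 times that of genes above 0.5. A limit set by duplicate removal may contribute. Counts of genes above 0.5 reads per base grew with library total at a median slope of 0.69. The slope was 1.01 for genes under 0.1, a gap of 0.315, and 0.384 for the 64 genes above 1. Mitochondrially encoded genes took 0.127% of counts in the largest library (5 nM at 6 h) and 0.169% in the smallest (15 nM at 12 h). Without that smallest library the gap was -0.063. Leaving it out narrows the range of totals, so that value cannot decide, and the part of such a limit stays open. A real difference in response between abundant and rare transcripts also stays open.

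In 35 genes both DMSO libraries had 0 counts and each treated library 10 or more, and 0 genes showed the opposite. Deeper treated libraries are argued against: no treated library total exceeded 1.154 times a DMSO total, where 3.33 times would be needed for 10 counts to become 3, and at its mean treated rate each of these genes would have 19.1 or more counts expected in each DMSO library. Genomic DNA or transcription outside genes stays open. At 12 h the summed CPM of these genes rose from 92.5 to 205 and 249 with dose, a ratio of 2.695 from 5 to 15 nM. The share of reads outside genes there fell from 15.1% to 14.7% and 14.0%, but at 6 h it did not fall steadily (15.6%, 15.2% and 15.5%). In each treated library that share was above that of the DMSO library of its time. The 14.0% in the 15 nM library at 12 h lies below the 14.4% of the DMSO library at 6 h. That DMSO library had 0 counts of these genes by the rule that chose them, so this comparison cannot decide. Cells of another type cannot be told apart from a change in the line itself by the marker lists, which mix several types: at most 30.8% of all listed members of any such list, untested ones included, were higher. That panobinostat raises silent genes in the line itself remains a hypothesis.

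Treated libraries differed between 12 h and 6 h in 6304 genes. Over these genes the DMSO libraries moved in the same direction by a median of 0.028 on the log2 scale, against 0.378 in the treated libraries, a ratio of 0.073. The genes were chosen by their change in the treated libraries, which raises that side. The DMSO library at 12 h also carries another run tag. The ratio therefore cannot decide on a run difference common to the 12 h libraries. The treated 12 h libraries carry a run tag of their own, so a difference of that run, if the tag marks one, cannot be told apart from longer exposure to panobinostat.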
